A study of Arabidopsis thaliana with 4 samples.

How the data were processed

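Whole seedlings of Arabidopsis thaliana accession Col-0 were either mock treated or dipped with their roots in an inoculum of Fusarium oxysporum, a soil fungus that enters through roots, and were taken 1 or 6 days later. Total RNA was depleted of ribosomal RNA and made into libraries with the SOLiD whole transcriptome kit, per the labels' protocols. Each of the 4 groups had 1 library, so none of the differences has a replicate check and no p-value is given.

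For each library the authors deposited the positions of aligned reads, 1 read per line, on the TAIR10 build named in the submitters' processing notes. The aligner, its filters and any trimming are not given in the sources used here. The intervals ran from 31 to 69 bases. The deposited score in the fifth column was a whole number that followed the first 4 bases and the strand of a read: among reads of 50 bases on nuclear chromosomes, 99.4% carried the commonest score of their 4 bases and strand in each library. Its meaning is not given in the sources used here, and it was not used in counting. The authors also deposited a table of regions between annotated genes for each library, whose last column held a signal that followed read coverage; how that signal was scaled is not given in the sources used here, and it entered no comparison. Some of these regions held no aligned read in any of the 4 read files, so those files may lack reads behind the regions: 7 of 923 merged nuclear regions had none.

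The reference sequence and annotation were those of assembly TAIR10.1, whose nuclear and chloroplast sequences have the lengths of TAIR10. Its mitochondrial sequence is another version and was not used here. Stretches of 50 bases that occur more than once made up 6.03% of the nuclear reference but held at most 0.0175% of the 50-base nuclear reads of a library, so reads from repeated sequence are nearly missing and genes with close copies are undercounted. Of 27444 nuclear protein-coding genes, 909 had under 80% of their 50-base stretches found once.

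A read was counted for a gene when it lay on the sense strand over exons of exactly 1 nuclear protein-coding gene. Counts were divided by median-of-ratios size factors. A gene was measured with at least 20 reads in the 2 libraries compared, and was counted as higher or lower when its fold was at least 2 and the exact 95% counting interval (Clopper-Pearson, on the share of the reads in 1 library) left out 1. Intervals cover counting error only, since each group has 1 library. Reads without molecular identifiers are not independent molecules, so the intervals may be too narrow even for counting error. Against a library with 0 reads the fold was computed against 3 counts per library and is given as at least that size; this bound allows for the count of 0 but not for counting error in the other library, which the exact interval used for calls and ranks includes. Log2 folds used 0.5 added reads. The fold of day 6 was set against that of day 1 with a normal interval on the log scale, for genes measured on both days; this reading of the minimum was settled after both counts had been seen, and the other reading is among the alternatives.

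Before the data were examined, 26 gene lists were fixed, with 403 different genes, all of which were in the annotation. The median log2 fold of a list was placed among 10000 random lists of the same size matched on mean expression in 20 bins, as a description of these libraries. The genes named were fixed by a rule: in each infection comparison the 10 higher and the 10 lower genes with the largest fold at the interval bound nearest 1, for each list up to 3 called members with the largest such bound or otherwise the member with most reads, up to 3 with the largest bound in each direction for the other parts (for regions and antisense reads the first of each direction is printed), and always PR1, PDF1.2A, PAD3, WRKY33, ERF72, RBOHD, RBOHF and LBD20. Genes outside the rule are said to be chosen after their values were seen.

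The counting was tested on simulated counts drawn from the real means, with 200 genes changed. The changed genes were taken from those with a mean of at least 20 normalised reads per library. Detection of measured genes with fewer reads was not tested. The simulated counts varied by counting error alone, which the interval assumes. The shares below therefore check the counting rule and do not give the rate of false calls between real libraries. For the day 1 comparison 88.0% of 50 genes changed 2.5-fold and all 50 changed 4-fold were called in the right direction, and 0.486% of 17713 unchanged genes were called. For the day 6 comparison the shares were 98.0% of 50 genes changed 2.5-fold and 0.402% of 18137 unchanged genes. In the simulated day 6 against day 1 difference of folds, with no gene changed, 1.25% of 17800 genes were called. Alternatives covered the scaling, the minimum number of reads, strand, introns, repeated positions, the fold and interval, depth and the mock library used as control. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, numba 0.67.0 and matplotlib 3.10.9 were used.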

Results

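The 4 libraries comprised mock-treated and Fusarium-inoculated Arabidopsis seedlings at 1 and 6 days post inoculation, 2 and 3 weeks old by the labels. The read files held 6937476 aligned reads for mock day 1, 9109007 for mock day 6, 6535652 for Fusarium day 1 and 7607998 for Fusarium day 6. Of these, 4065639, 4916004, 3846723 and 4964852 reads were counted for nuclear protein-coding genes. Chloroplast reads made up 25.3%, 30.2%, 24.96% and 17.8% of the aligned reads in the same order. Folds are given after size factors with their 95% counting interval in parentheses. No difference has a replicate check, so each compares 2 libraries and not the conditions at large. Where the mock library of the other day is the control, the 2 libraries also differ in plant age and day. A fold that changes with that control can therefore reflect age or day as well as the control library itself. Coordinates are on TAIR10.

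The first comparison asked which genes responded to the fungus at 1 day. In the Fusarium library 725 of 17921 measured genes were higher and 370 lower than in mock. Leading the higher genes were CYP82C2 (AT4G31970, chromosome 4, 15462350 to 15464563), a cytochrome P450 of indole defence metabolism, at 289-fold (51.4 to 11444), and CYP71A12 (AT2G30750, chromosome 2, 13099486 to 13101371), a cytochrome P450 of the camalexin branch, at 78.3-fold (51.1 to 127). The peroxidase PER4 was 287-fold (51.0 to 11359) higher, with 1 read in mock. AT1G26380 was 63.9-fold (42.0 to 102) higher and AT1G26410 109.7-fold (29.99 to 912) higher. AT3G29970, BGLU27 and GSTU12 had 0 reads in mock and were at least 43.7-fold, at least 32.7-fold and at least 34.4-fold higher. PRX62 was 59.1-fold (29.7 to 138) higher and the phytoglobin PGB1 42.3-fold (25.8 to 74.4) higher. With mock day 6 as control, CYP82C2, CYP71A12, PER4, AT1G26380 and AT3G29970 stood at 20.8-fold (12.6 to 36.9), 31.1-fold (24.1 to 40.8), 82.5-fold (31.9 to 305), 16.9-fold (13.7 to 21.0) and 30.2-fold (12.6 to 94.6), and BGLU27, GSTU12, PRX62 and PGB1 at 22.6-fold (9.34 to 71.2), 14.9-fold (7.26 to 35.5), 4.70-fold (3.82 to 5.81) and 10.98-fold (8.58 to 14.2). Leading the lower genes was the aquaporin TIP2;3 (AT5G47450, chromosome 5, 19248249 to 19249622), 12.2-fold (6.62 to 24.998) lower. AT3G45700 and MLO15 were 20.2-fold (5.26 to 172) and 16.4-fold (4.22 to 141) lower, and the xyloglucan-modifying XTH14 6.41-fold (4.16 to 10.3) lower. MLP329, MLP34 and RHS12 were 4.54-fold (3.66 to 5.69), 3.94-fold (3.56 to 4.37) and 5.97-fold (3.38 to 11.4) lower. AT4G35690, AT4G08410 and XTH13 each had 1 read in the Fusarium library and were 21.6-fold (3.51 to 889), 20.7-fold (3.34 to 852) and 19.7-fold (3.17 to 815) lower, and 47.4% of the 50-base stretches of AT4G08410 were unique. The control of day 6 gave TIP2;3, AT3G45700, MLO15, XTH14 and RHS12 folds of 7.999-fold (4.30 to 16.5), 11.8-fold (2.99 to 102), 7.74-fold (1.87 to 68.5), 3.46-fold (2.202 to 5.65) and 2.27-fold (1.21 to 4.53) lower, and AT4G35690 and XTH13 had under 20 reads in that comparison.

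Of the 26 gene lists, 17 had a median above the central 95% of random lists and 5 below it on day 1. Of the tryptophan and camalexin genes 14 of 15 measured were higher, with a median log2 fold of 1.79, and GSTF6 was 12.1-fold (9.96 to 14.8) higher. All 11 hypoxia genes were higher, with a median of 3.84, or 3.36 with members at 0 reads set to the floor. Against mock day 6, 9 of 11 were higher and 1, HRE1, was 2.17-fold (1.70 to 2.79) lower, with a median of 2.87. Among them ADH1, alcohol dehydrogenase, was 15.3-fold (12.1 to 19.5) higher and PDC1, pyruvate decarboxylase, 29.9-fold (20.4 to 45.7) higher. Of the jasmonate and ethylene defence genes 10 of 13 were higher, including the defensins PDF1.2B at 7.09-fold (5.18 to 9.88), PDF1.2C at 7.05-fold (5.36 to 9.41) and PDF1.3 at 5.17-fold (4.11 to 6.57). Against mock day 6 this list had 6 of 15 higher and 3 lower, and its median was 0.30 instead of 1.57. Of the glutathione transferases 9 of 11 were higher, GSTF7 by 19.7-fold (15.6 to 25.1) and GSTU10 by 8.83-fold (5.60 to 14.6), and of the class III peroxidases 6 of 7, with PER5 at least 25.9-fold higher. Of the WRKY factors 9 of 25 were higher, WRKY53 by 6.82-fold (4.24 to 11.5), WRKY51 by 6.56-fold (3.62 to 12.8) and WRKY45 by 4.82-fold (3.38 to 7.04). Of the indole glucosinolate genes 6 of 11 were higher, CYP81F2 by 18.6-fold (12.9 to 27.6), MYB122 by 11.1-fold (4.46 to 35.5) and MYB51 by 5.56-fold (4.25 to 7.36). With mock day 6 as control 9 WRKY factors were higher and 4 lower, and WRKY45 and MYB51 stood at 1.65-fold (1.304 to 2.09) and 1.37-fold (1.17 to 1.61), under the minimum fold.

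Of the salicylic acid defence genes 4 of 18 were higher on day 1, with FMO1 at 3.48-fold (2.05 to 6.16) and SARD1 at 2.56-fold (1.87 to 3.55), and of the pattern-triggered immunity genes 5 of 17, with PROPEP3 at 51.1-fold (8.75 to 2061), CML38 at 6.92-fold (4.07 to 12.6) and FRK1 at 6.39-fold (2.67 to 18.6). Against mock day 6, 10 of 18 salicylic acid defence genes were higher, with a median of 1.11 instead of 0.69, and FMO1 was 25.4-fold (8.29 to 126) higher. Of the NADPH oxidases 3 of 7 were higher, with RBOHA at 3.53-fold (2.09 to 6.25) and RBOHB at 2.08-fold (1.58 to 2.75). Of the jasmonate synthesis and response genes 5 of 24 were higher, LOX2 by 2.02-fold (1.92 to 2.12), JAZ1 by 2.58-fold (2.00 to 3.36) and LOX4 by 2.55-fold (1.81 to 3.65), and of the ethylene genes 4 of 14, ACS2 by 7.91-fold (3.58 to 20.6), ACO1 by 7.71-fold (5.24 to 11.7) and ETR2 by 4.08-fold (3.06 to 5.52). With mock day 6 as control, JAZ1, LOX4 and ETR2 were 1.48-fold (1.25 to 1.77), 1.26-fold (0.992 to 1.61) and 1.204-fold (1.02 to 1.43) lower, as was CML38 by 2.87-fold (2.31 to 3.61), and the pattern-triggered immunity list had 2 of 17 higher and 3 lower. Against mock day 6 the medians of the jasmonate synthesis and ethylene lists changed from 0.55 to -0.33 and from 0.37 to -0.61. Of the senescence genes 3 of 9 were higher, SAG13 by 3.16-fold (2.35 to 4.30), of the Fusarium resistance or susceptibility genes 2 of 13, RFO2 by 3.37-fold (1.295 to 10.3), and of the phenylpropanoid genes 1 of 16, CCR2 by 2.94-fold (2.07 to 4.23). With mock day 6 as control, 6 of 16 phenylpropanoid genes were higher, with a median of 0.93 instead of 0.44. The abscisic acid list had 2 of 17 higher, ANAC055 by 3.33-fold (2.31 to 4.91) and ANAC019 by 2.42-fold (1.15 to 5.45), the auxin list 1 of 19, GH3.3 by 2.501-fold (1.88 to 3.37), and the heat shock list 1 of 5, HSP90.1 by 2.24-fold (1.89 to 2.65). Against mock day 6, ANAC055, ANAC019 and GH3.3 were 1.21-fold (0.955 to 1.53), 1.92-fold (1.19 to 3.20) and 2.58-fold (2.16 to 3.10) lower, and HSP90.1 stood at 1.24-fold (1.08 to 1.41), under the minimum fold. The senescence, auxin, heat shock and Fusarium lists had medians of 0.31, 0.17, 0.55 and 0.29, and of -0.17, -0.57, -0.47 and -0.072 against mock day 6.

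Of 17 root markers 8 were lower on day 1 and 0 higher, with a median log2 fold of -0.74. PRX44 was 3.37-fold (2.64 to 4.34) lower, LRX1 4.07-fold (1.64 to 12.1) lower and EXPA7 2.72-fold (1.59 to 4.85) lower. The median was -0.091 against mock day 6, with 2 of 13 higher and 0 lower, and PRX44, LRX1 and EXPA7 did not pass. None of the 30 nuclear photosynthesis genes was higher or lower, with a median of -0.014 (0.35 against mock day 6, with 2 higher), and RCA, Rubisco activase, was 1.16-fold (1.14 to 1.18) lower. The phosphate starvation list had 1 of 10 lower, AT4 by 2.68-fold (1.93 to 3.78), and the cell cycle list 1 of 11, CDKB1;1 by 2.32-fold (1.29 to 4.35), neither of which passed against mock day 6. No member passed in the aliphatic glucosinolate list (14 genes), the flavonoid list (10), the circadian clock list (17) or the reference genes (10). MAM1 was 1.28-fold (1.19 to 1.37) lower, CHS 1.35-fold (1.25 to 1.46) lower, GRP7 1.25-fold (1.18 to 1.33) lower and ACT2 1.33-fold (1.26 to 1.40) lower. The aliphatic glucosinolate, flavonoid and phosphate medians were -0.22, -0.39 and -0.47, and 1.3001, 1.70 and 0.65 against mock day 6. Of all 104 list genes called on day 1, 58 kept the call with mock day 6 as control, and for 35 of these the fold changed by over 1.5 times.

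**Figure D1:**
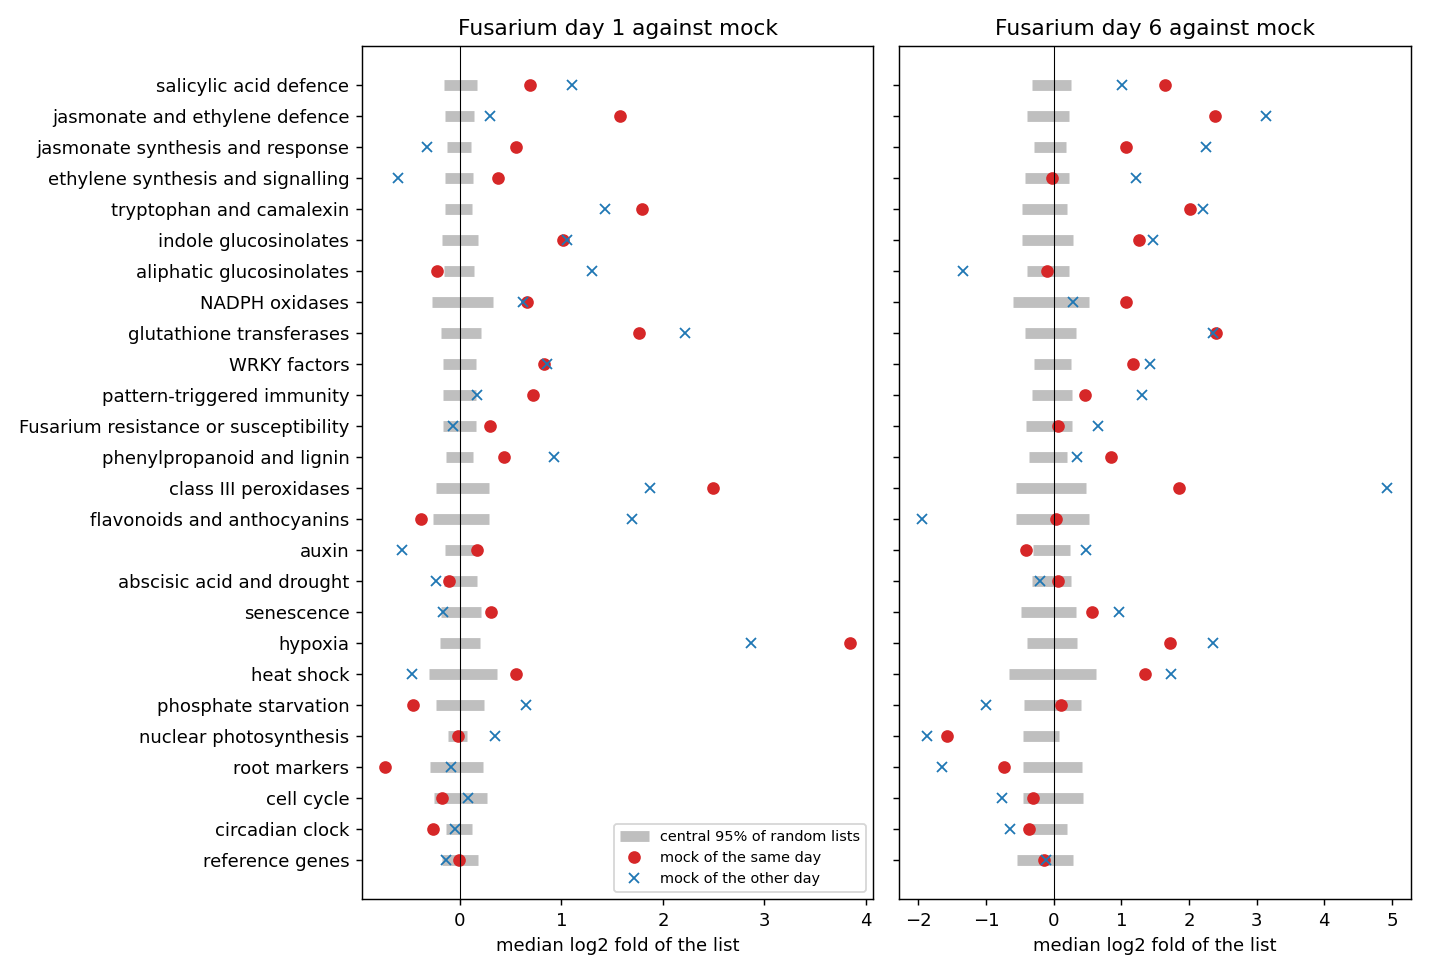
Median log2 fold of each of the 26 gene lists in the Fusarium library of day 1 (left) and day 6 (right), against the mock library of the same day (circles) and of the other day (crosses). Grey bars are the central 95% of random lists for the same-day control and apply to the circles only. The crosses have their own ranges, which are not drawn. On day 1 the pattern-triggered immunity cross at 0.17 lay inside its own range of -0.30 to 0.28. The hypoxia median of 3.84 lay farthest from 0 on day 1, and the nuclear photosynthesis median was -1.57 on day 6.

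The second comparison asked the same at 6 days. In the Fusarium library 1559 of 18137 measured genes were higher and 1523 lower than in mock day 6. Leading the higher genes was the defensin PDF1.2C (AT5G44430, chromosome 5, 17908850 to 17909507) at 74.4-fold (59.7 to 93.9), followed by CYP71A13 (AT2G30770, chromosome 2, 13109909 to 13111988), a camalexin enzyme, at 102-fold (55.1 to 213). AT4G33720 was 296-fold (52.8 to 11728) higher and AT4G36700 196-fold (34.7 to 7758) higher, each with 1 read in mock. CYP82C2 was 85.6-fold (52.6 to 150.2) higher, AT1G47395 118-fold (45.6 to 433), the iron-deficiency regulator bHLH38 75.5-fold (39.6 to 166), TPS04 69.2-fold (34.9 to 161), scpl30 75.8-fold (34.6 to 207) and the defensin PDF1.2A 45.0-fold (39.0 to 52.3). Leading the lower genes was AT3G25190 (chromosome 3, 9174398 to 9175866), 35.2-fold (19.9 to 68.6) lower, then the iron-sulphur protein NEET, 72.7-fold (19.7 to 606) lower. The light-harvesting genes LHB1B1 and LHCB2.3 were 21.7-fold (19.0 to 24.9) and 16.2-fold (12.6 to 21.1) lower. MLP329, MLP328 and AT1G12080 were 27.5-fold (18.6 to 42.4), 15.72-fold (12.8 to 19.6) and 25.8-fold (14.9 to 49.0) lower. BXL2 was 16.7-fold (14.4 to 19.5) lower, XTH17 at least 16.99-fold lower, and the ferritin FER1 13.6-fold (11.4 to 16.4) lower. With mock day 1 as control, CYP71A13, AT4G33720, AT4G36700, AT1G47395 and bHLH38 stood at 46.4-fold (29.6 to 77.4), 28.5-fold (14.8 to 63.0), 33.9-fold (14.3 to 106), 15.1-fold (10.3 to 23.2) and 8.55-fold (6.67 to 11.1) higher, CYP82C2 and scpl30 at 1189-fold (213 to 47003) and 395-fold (70.5 to 15615) higher, and TPS04 at 9.42-fold (7.07 to 12.8) higher. In that comparison LHCB2.3, MLP328, BXL2 and FER1 were 28.8-fold (22.5 to 37.4), 10.2-fold (8.23 to 12.8), 4.05-fold (3.43 to 4.81) and 4.13-fold (3.39 to 5.07) lower. Counted against both mock libraries, a reading chosen after the data were seen, 1031 genes were higher and 938 lower on day 6, and 397 were higher and 89 lower on day 1.

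On day 6, 14 lists had a median above and 4 below that range. Of 30 nuclear photosynthesis genes 24 were lower on day 6 and 0 higher, with a median log2 fold of -1.57, and 29 were lower against mock day 1. LHCB1.1 was 6.12-fold (5.77 to 6.495) lower, LHCB2.2 6.24-fold (5.53 to 7.07) and LHCB3 5.03-fold (4.76 to 5.32), with 79.5% of the 50-base stretches of LHCB1.1 and 70.5% of those of LHCB2.2 unique. In the same library the chloroplast share of reads was 17.8%, against 30.2% in mock day 6 and 25.3% in mock day 1, and the root markers had a median of -0.73. The share counts all chloroplast reads, ribosomal RNA included. Of 7 chloroplast ribosomal RNA genes, 5 were higher and 0 lower in mock day 6 than in mock day 1. Of the jasmonate synthesis and response genes 14 of 26 were higher, CORI3 by 26.0-fold (19.1 to 36.2), LOX2 by 10.9-fold (10.3 to 11.6) and VSP1 by 11.7-fold (10.3 to 13.4). Against mock day 1, 22 of 26 genes of this list were higher, with a median of 2.25 instead of 1.06. Of the salicylic acid defence genes 11 of 18 were higher, with PR2 at 13.5-fold (10.6 to 17.42) and WRKY38 at least 19.1-fold higher. PR2 stood at 1.67-fold (1.501 to 1.86) against mock day 1, under the minimum fold. Of the jasmonate and ethylene defence genes 9 of 15 were higher, of the tryptophan and camalexin genes 13 of 15, with CYP71A12 at 26.4-fold (20.5 to 34.7), and of the indole glucosinolate genes 7 of 11, with SOT16 at 2.97-fold (2.54 to 3.48) and CYP83B1 at 2.84-fold (2.63 to 3.08). Of the glutathione transferases 11 of 12 were higher, with GSTU10 at 8.62-fold (5.97 to 12.8) and GSTU4 at 8.45-fold (6.75 to 10.7), and of the class III peroxidases 6 of 7, with PRX52 at 123-fold (21.6 to 4881). Of the WRKY factors 14 of 26 were higher and 1 lower.

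Of the phenylpropanoid genes 8 of 16 were higher on day 6, with 4CL2 at 4.61-fold (3.55 to 6.06), CCR2 at 3.18-fold (2.43 to 4.21) and 4CL1 at 2.99-fold (2.60 to 3.45), against 2 of 16 higher and 1 lower with mock day 1 as control, where 4CL2 and 4CL1 stood at 1.85-fold (1.52 to 2.26) and 1.66-fold (1.47 to 1.87). Of the hypoxia genes 8 of 11 were higher and 1 lower, with PDC1 at 5.08-fold (3.80 to 6.90), PCO1 at 4.90-fold (3.34 to 7.39) and HRA1 at 4.82-fold (3.42 to 6.94). Of the NADPH oxidases 4 of 7 were higher and 1 lower. Of the heat shock genes 5 of 8 were higher and 1 lower, with HSFA2 at 3.75-fold (2.07 to 7.30). Of the pattern-triggered immunity genes 5 of 19 were higher and 2 lower, with NHL10 at 54.4-fold (9.39 to 2185) and PEPR2 at 3.90-fold (3.04 to 5.05). Against mock day 1 this list had 11 of 19 higher and 0 lower, with a median of 1.31 instead of 0.47. The senescence list had 3 of 10 higher and 1 lower: the protease gene SAG12 was at least 32.9-fold higher and SEN1 4.28-fold (3.96 to 4.63) lower, but SEN1 was 1.05-fold (0.945 to 1.17) higher against mock day 1. The Fusarium resistance or susceptibility list had 3 of 13 higher, RFO2 by 5.07-fold (2.36 to 12.5). Of the root markers 5 of 12 were lower, PRX44 by 5.80-fold (3.79 to 9.19), EXPA18 by 4.34-fold (1.40 to 17.8) and ESB1 by 2.17-fold (1.66 to 2.86), with 0 higher. With reads of both strands counted, the log2 fold of ESB1 was 1.47.

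Other lists held members of both directions on day 6. The ethylene list had 2 of 16 higher and 2 lower. ACS2 and ACS7 were 7.79-fold (4.76 to 13.5) and 21.2-fold (3.44 to 874) higher. ACS8 was 2.90-fold (2.12 to 4.02) lower, but 7.47-fold (3.22 to 21.2) higher against mock day 1. The abscisic acid list had 3 of 18 higher and 4 lower. ANAC019 was 4.08-fold (3.07 to 5.51) higher, ERD10 4.35-fold (3.71 to 5.13) lower and COR47 4.18-fold (3.83 to 4.57) lower. The auxin list had 1 of 20 in each direction, GH3.3 3.31-fold (3.00 to 3.66) higher and TAA1 2.81-fold (1.69 to 4.83) lower. The auxin median was -0.42, and 0.47 against mock day 1, with 7 of 19 higher and 1 lower. Against mock day 1 the ethylene list had 9 of 16 higher and 0 lower, with a median of 1.21. The aliphatic glucosinolate list had 3 of 14 higher and 2 lower, SOT17 4.97-fold (4.097 to 6.06) higher and MAM1 3.15-fold (2.85 to 3.49) lower, and the flavonoid list 2 of 9 in each direction. Against mock day 1, 9 of 14 aliphatic glucosinolate genes and 6 of 10 flavonoid genes were lower and 0 higher, with medians of -1.34 and -1.94. The phosphate starvation list had 2 of 8 higher and 1 lower, PAP17 5.41-fold (4.02 to 7.41) higher and AT4 4.93-fold (3.02 to 8.45) lower, and the cell cycle list 2 of 11 higher and 3 lower, TSO2 4.12-fold (3.12 to 5.52) higher and KNOLLE 2.60-fold (1.99 to 3.41) lower. Against mock day 1, 5 of 10 phosphate starvation genes and 3 of 11 cell cycle genes were lower and 0 higher, with medians of -1.002 and -0.77. The clock list had 3 of 17 lower, RVE1 by 3.28-fold (2.73 to 3.96), LNK2 by 2.83-fold (2.65 to 3.02) and PRR7 by 2.43-fold (2.23 to 2.65). ERD10, TAA1, SOT17, PAP17, TSO2, LNK2 and PRR7 kept their direction but stayed under the minimum fold against mock day 1. Of all 186 list genes called on day 6, 143 kept the call with mock day 1 as control, and for 77 of these the fold changed by over 1.5 times. None of the 10 reference genes passed, with a median of -0.15.

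Among the genes named in advance, PR1 (AT2G14610, chromosome 2, 6241640 to 6242541), a marker of salicylic acid defence, was 2.02-fold (1.58 to 2.60) higher on day 1 and 23.5-fold (14.3 to 41.5) higher on day 6, with 100, 16, 190 and 408 reads in mock day 1, mock day 6, Fusarium day 1 and Fusarium day 6. The mock of the other day gave PR1 folds of 14.6-fold (8.75 to 26.0) on day 1 and 3.27-fold (2.62 to 4.11) on day 6. The defensin PDF1.2A (AT5G44420, chromosome 5, 17906968 to 17907638) was 4.50-fold (3.79 to 5.35) and 45.0-fold (39.0 to 52.3) higher. PAD3 (AT3G26830, chromosome 3, 9887917 to 9889791), the last enzyme of camalexin synthesis, was 9.71-fold (7.32 to 13.1) and 17.63-fold (14.3 to 22.0) higher. WRKY33 was 3.17-fold (2.78 to 3.63) higher on day 1 and stood at 1.59-fold (1.44 to 1.75) on day 6, under the minimum fold. Against the mock of the other day it stood at 1.70-fold (1.54 to 1.89) on day 1, under the minimum fold, and was 2.96-fold (2.60 to 3.37) higher on day 6. The NADPH oxidase RBOHD was 2.76-fold (2.46 to 3.09) and 2.66-fold (2.45 to 2.90) higher, and RBOHF was 2.13-fold (1.74 to 2.61) higher on day 6 but stood at 1.59-fold (1.24 to 2.04) on day 1, under the minimum fold. RBOHD stood at 1.81-fold (1.65 to 1.99) on day 1 against mock day 6, also under it, and at 4.06-fold (3.66 to 4.51) on day 6 against mock day 1. ERF72 was 1.11-fold (0.976 to 1.27) and 1.88-fold (1.71 to 2.08) lower, which did not reach the minimum fold, but 2.18-fold (1.95 to 2.45) lower on day 1 against mock day 6, and 1.04-fold (0.923 to 1.17) higher on day 6 against mock day 1. LBD20 had 0 reads in all 4 libraries and was not detectable at this depth.

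**Figure D2:**
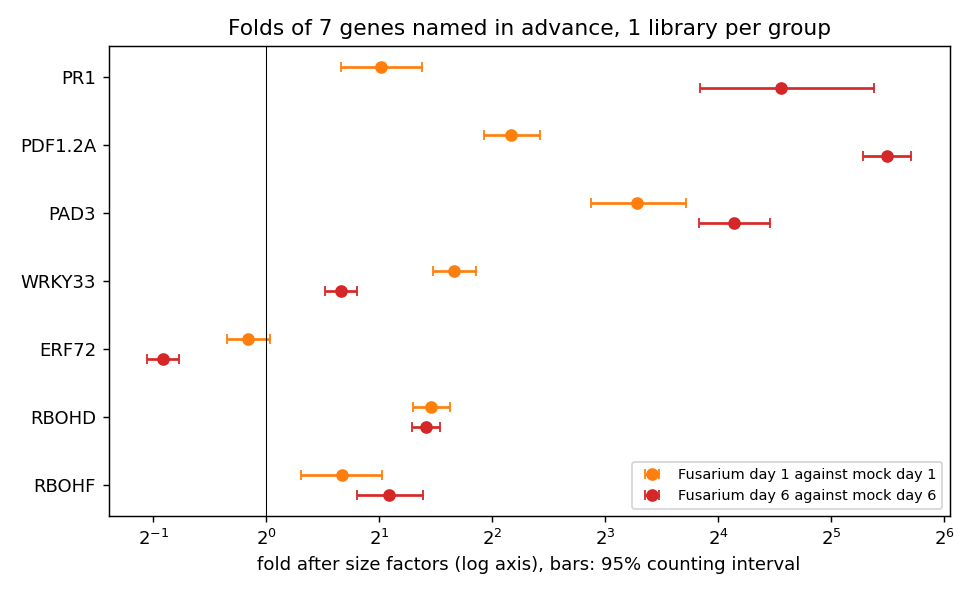
Folds of 7 genes named in advance in the Fusarium library against the mock library of the same day, on a log axis, with 95% counting intervals as bars and 1 library per group. PDF1.2A lay at 4.50-fold on day 1 and 45.0-fold on day 6, and ERF72 lay below 1 on both days.

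Of the 17467 genes measured on both days, 432 were higher and 150 lower on both, where independent lists would share 51.6 and 24.8. The 2 comparisons share no library. Across genes, which are not independent replicates, the log2 folds had a Pearson correlation of 0.50 and a Spearman correlation of 0.30. Against both mock libraries on both days, 290 genes were higher and 57 lower. The fold was at least 2 times higher on day 6 than on day 1 for 900 genes and lower for 1381. Among the higher were TPS04, TAT3 and AT2G30766, at 69.2-fold (34.9 to 161), 29.3-fold (22.1 to 39.6) and 55.0-fold (31.3 to 107) on day 6 and 1.40-fold (0.958 to 2.06), 1.32-fold (1.11 to 1.57) and 1.51-fold (1.27 to 1.80) on day 1. All of these were lower in mock day 6 than in mock day 1, by 7.35-fold (3.46 to 17.9), 5.72-fold (4.204 to 7.91) and 21.1-fold (11.9 to 41.5). Against mock day 1 their day 6 folds were 9.42-fold (7.07 to 12.8), 5.12-fold (4.48 to 5.88) and 2.60-fold (2.24 to 3.04), and their day 1 folds against mock day 6 were 10.3-fold (4.93 to 24.8), 7.54-fold (5.58 to 10.4) and 31.9-fold (18.0 to 62.4). AT2G30766 overlaps CYP71A13 on the opposite strand. Among the lower were NEET, LHB1B1 and LHCB2.3, whose day 1 folds lay between 1.17-fold lower and 1.05-fold higher.

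**Figure D3:**
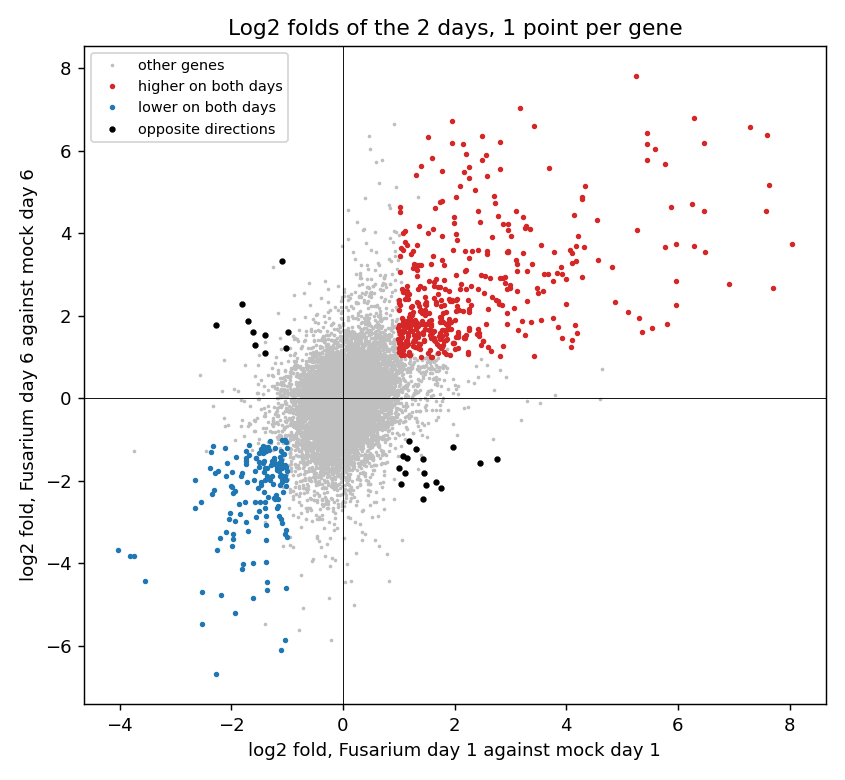
Log2 fold of each of the 17467 genes measured on both days, day 1 on the horizontal and day 6 on the vertical axis, 1 point per gene. The 432 genes higher on both days are red, the 150 lower on both days blue and the 26 called in opposite directions black.

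The mock libraries of the 2 days, which differ in plant age, were compared as a yardstick without the fungus. In mock day 6, 1093 of 17960 measured genes were higher and 1244 lower than in mock day 1. RRTF1, PHI-1 and DDF1 were 69.1-fold (23.4 to 338), 18.3-fold (13.2 to 26.2) and at least 15.9-fold higher. BHLH101 and FRO2, genes of iron homeostasis, were 41.5-fold (13.8 to 204) and 24.0-fold (15.1 to 40.2) lower, and the flavonol regulator MYB12 47.8-fold (12.8 to 401) lower. This comparison shares a library with each infection comparison, so no correlation with them was read.

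The deposited regions between genes numbered 568 for mock day 1, 673 for mock day 6, 537 for Fusarium day 1 and 826 for Fusarium day 6. At least 50% of each region was shared for 341 regions between mock day 1 and Fusarium day 1, and for 408 between mock day 6 and Fusarium day 6. The mock libraries shared 356 with each other, and the Fusarium libraries 361. Mock day 1 shared 356 with Fusarium day 6, and mock day 6 shared 346 with Fusarium day 1. Merged, the deposited regions made 923 nuclear regions, of which 803 overlapped a gene of the newer annotation. By reads, 16 of 427 measured regions were higher and 10 lower in Fusarium day 1, and 58 of 578 higher and 44 lower in Fusarium day 6. The leading region of day 1 was on chromosome 2, 10770730 to 10770947, overlapping AT2G25297, at least 11.007-fold higher, with 0, 3, 31 and 38 reads in mock day 1, mock day 6, Fusarium day 1 and Fusarium day 6. The leading lower region was on chromosome 1, 18428009 to 18428173, overlapping the snoRNA gene AT1G07593, 2.199-fold (2.11 to 2.29) lower, but 1.13-fold (1.08 to 1.18) lower with mock day 6 as control, under the minimum fold. On day 6 a region on chromosome 1, 4663219 to 4663490, overlapping AT1G13609, was 60.9-fold (29.3 to 152) higher, and one on chromosome 5, 7891102 to 7891360, overlapping the long non-coding gene AT5G03615, 20.6-fold (5.32 to 176) lower. Their reads in the same order were 50, 7, 164 and 462, and 1, 38, 7 and 2. Against mock day 1 the first was 7.39-fold (5.52 to 10.11) higher, and the second had under 20 reads, so its fold rests on the mock library of day 6. Reads of both strands were counted for regions, and with each position counted once the numbers of regions were lower by over 1.5 times.

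Reads antisense to protein-coding exons made up 0.875%, 0.989%, 0.778% and 0.922% of nuclear reads in mock day 1, mock day 6, Fusarium day 1 and Fusarium day 6. Of 404 genes measured, 21 were higher and 11 lower in antisense reads on day 1, and of 733, 60 were higher and 98 lower on day 6. AT1G13609 (chromosome 1, 4662698 to 4663253) had 75, 8, 260 and 1004 antisense reads and 0 sense reads in the 4 libraries, and its antisense reads were 116-fold (58.5 to 269) higher on day 6, or 10.7-fold (8.47 to 13.7) with mock day 1 as control. Those of PDV2 (chromosome 2, 6983846 to 6985620), whose neighbour is PGB1, were at least 8.17-fold higher on day 1, and those of AT1G76880 4.69-fold (1.57 to 18.9) lower. With mock day 6 as control those of PDV2 were 5.65-fold (2.0997 to 19.0) higher, and AT1G76880 had under 20. On day 6 those of AT1G02620, with 4, 33, 3 and 0 reads in the 4 libraries, were at least 11.9-fold lower, but had under 20 with mock day 1 as control. The annotated strand of AT1G13609 is left open.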

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

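All tests in this part were chosen after the results were seen. On the 2 days 26 genes were called in opposite directions, 16 of them higher on day 1 and lower on day 6, and 10 the reverse, where independent lists would share 57.9 and 22.1. This difference between the days was not tested, since each group has 1 library. Among these genes, chosen after their values were seen, CML38 had 16, 367, 104 and 143 reads and HRE1 30, 242, 91 and 64 in mock day 1, mock day 6, Fusarium day 1 and Fusarium day 6, and CML38 was 7.15-fold (4.26 to 12.9) higher on day 6 against mock day 1. Of nuclear genes that do not code for protein, which lie outside the main measurement, 21 of 666 measured were higher than in mock and 32 lower on day 1, and 56 of 738 were higher and 90 lower on day 6.

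Nuclear photosynthesis genes were lower in Fusarium day 6, 24 of 30. That 29 of 30 were lower against mock day 1 argues against an unusual mock day 6 library. The highest list median under the other scalings was -1.47, so the choice among these scalings does not account for the difference. All of them rest on the same nuclear counts and move every gene alike by a small step, so they cannot test scaling beyond that choice. A lower share of shoot tissue may contribute. Root markers had a median log2 fold of -0.73 where a shift in tissue alone would raise them, but they were also lower on day 1, where photosynthesis genes did not differ (though the day 1 median of the root markers was -0.091 against mock day 6), so they do not follow tissue share alone and the explanation stays open beside a response to the fungus.

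Hypoxia genes were higher in Fusarium day 1, 11 of 11. Against mock day 6, 9 of 11 were higher and 1, HRE1, lower, and the median log2 fold was 2.87 instead of 3.84, which argues against an unusual mock day 1 library as the whole cause. The photosynthesis median of -0.014 argues against a higher share of root tissue. In the separate Fusarium library of day 6, 8 of 11 were higher and 1 lower than in mock day 6, with a median of 1.73. Against mock day 1, 9 of 10 were higher there and 0 lower, with a median of 2.35. Low oxygen in the day 1 library alone would not account for these day 6 values. For the size of the day 1 difference, low oxygen during handling or growth of that library cannot be told apart from a response to the fungus, with 1 fusarium library of day 1.

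In mock day 6, 1093 genes were higher and 1244 lower than in mock day 1. Between the Fusarium libraries of day 6 and day 1, which share no library with them, 319 genes were higher and 475 lower in the same direction, at least 4.25 times the overlap of independent lists, which is consistent with an effect of age or day common to both treatments for part of the genes. A technical difference between the days cannot be told apart from age, since the labels give no batch and each day has 2 libraries.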

How the results depend on the processing

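No paired analysis was possible because each group has 1 library. Counts of genes are given in the order higher and lower on day 1, higher and lower on day 6, higher and lower on both days, fold higher and lower on day 6 than day 1, and higher and lower in mock day 6 than mock day 1. They were 725, 370, 1559, 1523, 432, 150, 900, 1381, 1093 and 1244. With at least 100 reads they were 341, 85, 880, 859, 210, 32, 400, 792, 725 and 548, with a 1.5-fold minimum 1273, 745, 2690, 2903, 747, 322, 1796, 2587, 2423 and 2559, and with a 4-fold minimum 239, 69, 600, 351, 148, 23, 215, 280, 235 and 207, as fewer or more genes can pass. With the wider counting interval 186 genes were lower on day 1, 88 lower on both days, and 477 and 907 had a fold higher and lower on day 6. With the mock library of the other day, 1339 and 841 genes were higher and lower on day 1, 2348 lower on day 6, and 2406 and 3224 had a fold higher and lower on day 6. Each swapped control differs from its Fusarium library in plant age and day too. In the difference of folds, the changes from day 1 to day 6 in mock and in Fusarium are then multiplied. The main reading divides one by the other, so the swapped counts do not measure a response to the fungus alone. What moved the other counts was not tested. The mock comparison has no alternative with a swapped control.

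Alternatives chosen after seeing the data were 50-base intervals, genes with unique sequence, both mock libraries, and 20 reads over the 4 libraries. With 50-base intervals 89 genes were lower on both days. Against both mock libraries 397 and 89 genes were higher and lower on day 1, 1031 and 938 on day 6, and 57 lower on both days. With 20 reads over the 4 libraries, the reading seen first, 1056 and 1491 genes had a fold higher and lower on day 6. Under scaling to total protein-coding reads, trimmed mean of M values, no minimum, both strands, whole genes, thinned reads and unique genes, these counts stayed within 1.5 times. Scaling to total reads moved all day 6 log2 folds by 0.10, with 1800 higher and 1290 lower. With each position counted once, 9 and 2 regions were higher and lower on day 1, 38 and 19 on day 6, and 24 higher in mock day 6.

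With the mock of the other day, 3 lists lay below the random lists on day 1 against 5, and 7 on day 6 against 4. Of the list medians outside the central 95% of random lists, 9 changed sign on day 1: jasmonate synthesis to -0.33, ethylene to -0.61, aliphatic glucosinolates to 1.3001, Fusarium to -0.072, flavonoids to 1.70, auxin to -0.57, senescence to -0.17, heat shock to -0.47 and phosphate to 0.65. On day 6 that of auxin changed to 0.47. Medians inside that range also changed sign, on day 1 nuclear photosynthesis from -0.014 to 0.35 and cell cycle from -0.18 to 0.081, and on day 6 ethylene from -0.030 to 1.21, flavonoids from 0.039 to -1.94, phosphate from 0.11 to -1.002 and abscisic acid from 0.069 to -0.21. Other medians that entered or left the range were pattern-triggered immunity, to 0.17, root markers, to -0.091, and circadian clock, to -0.046, on day 1, and aliphatic glucosinolates, to -1.34, NADPH oxidases, to 0.28, Fusarium, to 0.66, phenylpropanoid, to 0.34, and cell cycle, to -0.77, on day 6. Of all measured genes, 37 of the 725 higher and 4 of the 370 lower on day 1 were called in the opposite direction with that control. On day 6 these were 11 of 1559 and 26 of 1523. Among called genes named by the rule, log2 folds that changed sign on day 1 were JAZ1 -0.57, ANAC019 -0.93, LOX4 -0.33, CML38 -1.52, GH3.3 -1.36, ANAC055 -0.27, ETR2 -0.27, SAG21 -0.88 and ORE1 -0.37. Those named by the rule that changed sign on day 6 were DDF1 2.85, PHI-1 1.31, CML38 2.80, RRTF1 3.31, SEN1 0.073, ACS8 2.80 and UF3GT -0.62. ESB1 changed to 1.47 on day 6 with reads on both strands. Of 284 values of named genes, 47 that were called against the mock of the same day did not keep that call with the mock of the other day. Of these, 16 changed sign and 31 kept their direction. Values with no call against the mock of the same day are not among the 47. Depth limits genes with few reads: 85 of the 370 genes lower on day 1 had at least 100 reads.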

Other observations

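The genes of this paragraph were chosen after their values were seen and were not tested as a group. The iron-deficiency regulators bHLH38, bHLH39, BHLH100 and BHLH101 were 75.5-fold (39.6 to 166), 17.38-fold (11.7 to 26.9), 51.1-fold (30.2 to 93.8) and 63.6-fold (21.5 to 311) higher in Fusarium day 6 than in mock day 6, and the ferritin FER1 13.6-fold (11.4 to 16.4) lower. All of these regulators were lower in mock day 6 than in mock day 1, bHLH39 by 3.90-fold (2.49 to 6.30) and BHLH101 by 41.5-fold (13.8 to 204). Against mock day 1, bHLH38 was 8.55-fold (6.67 to 11.1) higher on day 6, and BHLH101 stood at 1.53-fold (1.21 to 1.95), under the minimum fold. The uptake genes FRO2 and IRT1 had 395, 19, 312 and 27 and 290, 22, 240 and 39 reads in mock day 1, mock day 6, Fusarium day 1 and Fusarium day 6, and did not pass on day 6, at 1.31-fold (0.702 to 2.49) and 1.63-fold (0.946 to 2.89). With mock day 1 as control, FRO2 was 18.3-fold (12.4 to 28.1) lower on day 6.

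Of 194 measured snoRNA genes 17 were lower and 0 higher in Fusarium day 1, and of 195 on day 6, 28 were lower and 3 higher. These classes were not counted against the mock of the other day. Regions over the snoRNA genes AT1G07593 and AT3G07735 were 1.13-fold (1.08 to 1.18) and 1.48-fold (1.32 to 1.66) lower on day 1 against mock day 6, under the minimum fold. On day 6, 10 of 22 snRNA genes were lower and 0 higher. Of 23 chloroplast tRNA genes 11 were lower and 1 higher, and of 7 chloroplast rRNA genes 4 and 0. The chloroplast rRNA genes had a median log2 fold of -1.19 in this comparison. In mock day 6 against mock day 1, 5 of these 7 were higher and 0 lower, with a median of 1.28. Their lower reads in Fusarium day 6 may therefore rest on the mock day 6 library. Of 83 measured chloroplast protein-coding genes 26 were lower and 0 higher in Fusarium day 6, with a median log2 fold of -0.78, and 0 of 82 differed on day 1. The long non-coding gene AT1G07367 had 8, 1, 35 and 156 reads in mock day 1, mock day 6, Fusarium day 1 and Fusarium day 6, and AT1G09505 had 2, 0, 21 and 82. These genes were taken by the rule used for the other parts, chosen after the data were seen.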
